A study of Homo sapiens with 16 samples.

How the data were processed

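RNA recovered by IgG or HuR immunoprecipitation from synchronized U2OS cells with control or MIR100HG siRNA was amplified from an oligo-dT primer and hybridised to Illumina bead arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The series' design text calls the 4 samples of each group biological replicates.

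The deposited intensity values are bead summaries per probe on a linear scale, not normalized between arrays, exported with GenomeStudio 2011.1 per the submitters' processing notes. Each has a detection p-value, per the file headers, which compares the probe with negative controls of its array. The series' value table holds a deposited score per probe, from its values a z-score per array; how it was made is not given in the sources used here, and its direction follows the intensities. Of its 16 columns 15 correlated with the log2 intensity of their own array (lowest r 0.997 across probes), and the column of the IgG IP with MIR100HG siRNA, replicate 1, did so at 0.0066, so this column was not used.

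Of 47231 probes, 30113 had 1 gene in the platform annotation, 8 had several and 17110 are unnamed here. Symbols of 30074 probes were updated through their gene identifiers, and 39 found no match and kept the annotation's symbol. Intensities were background corrected and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), with negative controls inferred from the detection p-values and an offset of 16. Quantile normalization gives every array the same distribution, so it can hide or create differences where arrays differ in their amount of signal. Probes with a detection p under 0.01 on at least 4 of 16 arrays were kept (1438 probes, 3.04%), and the probe with the highest mean stood for a gene with several. This left 825 named genes and 562 unnamed probes.

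The test was limma (lmFit, contrasts.fit, eBayes) with 4 group means over all 16 arrays and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Contrasts were HuR minus IgG for each siRNA, their difference (the interaction), their mean, and MIR100HG minus control siRNA within each IP type. Gene lists, 25 in all, were fixed before the data were examined, as were the contrasts, the alternatives and the rule for named genes, except where stated. In the other 16 lists fewer than 3 members were tested and only counts are given; 9 had at least 3 tested members and were tested with camera at a correlation of 0.01, with an estimated correlation, and with fry. Set scores and detected probes were compared by two-sided exact permutation.

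Named genes were, per contrast, up to 8 rises and 8 falls with the largest log2 difference past the threshold, detected at p under 0.01 on at least 2 arrays of every group and without overlap of the groups' values; up to 4 members of each list past the threshold, or up to 2 with the smallest p if none passed; up to 2 genes per direction of each enrichment detected in 1 group alone, given as bounds; and MIR100HG and ELAVL1. Symbols beginning with LOC or HS. were passed over, and so were unnamed probes. Several probes of GAPDH, RPS29, ACTB, ROCK2, EEF1A1, CCND2, EIF4G2, DCBLD2 and RPL11 passed the filter; in the HuR enrichment with control siRNA those of ACTB gave 0.91, 2.84 and 4.06 and those of ROCK2 1.93 and -0.08.

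The fit was tested on simulated data over 1387 genes, with 50 genes changed by each of 0.5, 1, 2 and 3 on the log2 scale. For the HuR enrichment with control siRNA it recovered 26%, 90%, 100% and 100% of them, and 4.24% of the calls were unchanged genes. For the enrichment with MIR100HG siRNA it recovered 18%, 90%, 98% and 100% (5.56% of the calls were unchanged genes), and for the interaction 8%, 60%, 92% and 98% (3.01%). For the siRNA effect in HuR IPs it recovered 20%, 78%, 100% and 100% (3.87%), and in IgG IPs 24%, 90%, 100% and 100% (1.88%). In 100 simulations without a change the set score passed in 3% and camera in 2%, and both passed in 100% of 20 with a shift of 0.5. The simulated genes were independent with equal spread in every group, which the arrays were not. The estimated correlation was 0.335 for the ribosomal protein list and ran from -0.225 to 0.597 over the tested lists. The set score of HuR-enriched genes had an SD of 0.61 in HuR IPs with MIR100HG siRNA and of 0.051 to 0.094 in the other groups. The simulated percentages therefore need not hold for the arrays.

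Alternatives covered background correction, normalization, the deposited scores, the filter, probes per gene, array weights, an intensity trend, a fold threshold, the groups in the fit, the replicate number as a block, and leaving out each array. Where quantile normalization within each IP type is named, median centring of every array followed it. Slides are not given in the sources used here, so no slide block was fitted. No replicates were found to be duplicates: arrays of a group shared between 8.25% and 11.0% identical intensities. The figures were drawn with matplotlib 3.10.9.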

Results

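The arrays measured RNA recovered by immunoprecipitation (IP) from U2OS cells, a human osteosarcoma line, that had been synchronized in the cell cycle. The labels do not give the phase of each sample. Cells received a control siRNA or an siRNA against the long noncoding RNA MIR100HG for 48 hours, and RNA was collected with an antibody against HuR, the RNA-binding protein encoded by ELAVL1, or with IgG as background. The protocol spells the siRNA target mIR-110HG, while titles and stated aim name MIR100HG, and which transcript was hit could not be checked. There were 16 single-colour bead arrays in 4 groups of 4 biological replicates. The series title names the question: whether MIR100HG changes the interaction of HuR with its target mRNAs.

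Most probes lay at background on every array. The median deposited intensity per array was between 42 and 50, and between 553 and 2592 of 47231 probes were detected at a detection p under 0.01, where 472 would be by chance. Detected probes averaged 916 ± 122 (SD, n = 4) in IgG IPs with control siRNA, 737 ± 196 in IgG IPs with MIR100HG siRNA, 1139 ± 276 in HuR IPs with control siRNA and 1185 ± 945 in HuR IPs with MIR100HG siRNA. None of the 4 differences between these groups passed a two-sided exact permutation test (lowest p = 0.171, adjusted p = 0.457; the smallest p that 4 against 4 arrays allow is 0.0286). Replicate 2 of the HuR IPs with MIR100HG siRNA stood apart, with 2592 detected probes and a highest intensity of 6370. Replicates 1, 3 and 4 of that group had 563, 824 and 761 detected probes and highest intensities of 327, 314 and 334. Without replicate 2 the difference in detected probes between HuR IPs with MIR100HG and control siRNA was -423.25, against 45.75 with it, and against IgG IPs it was -21.25, against 447.75. The first of these was -83.3 without replicate 4 of the HuR IPs with control siRNA. The median intensity averaged 49 ± 1.15 (SD, n = 4) in HuR IPs with MIR100HG siRNA. It averaged 43.75 ± 1.26 in IgG IPs with that siRNA and 46.25 ± 0.5 in HuR IPs with control siRNA. Both differences had an exact permutation p of 0.0286 (adjusted p = 0.0571). P-values here measure the spread between these samples. The IP numbers of each group are consecutive, so an order of handling that followed them could not be told apart from antibody and siRNA. The number of arrays and the low signal limit the precision of every comparison.

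MIR100HG itself, the siRNA target, was not detected: its probe (ILMN_3244176) had a detection p of 0.05 or more on all 16 arrays. Its mean intensity was 46.5 ± 1.91 (SD, n = 4) and 43.5 ± 1.91 in IgG IPs with control and MIR100HG siRNA, and 46.8 ± 4.79 and 51.3 ± 3.40 in HuR IPs. Depletion therefore could not be checked on these arrays. ELAVL1, which encodes HuR, was likewise detected on 0 of 16 arrays (probe ILMN_1764873, lowest detection p 0.117), and no fold is given for either gene.

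In control-siRNA cells, HuR IPs held more ITGB1, ACTB, CCND2 and CDH2 mRNA than IgG IPs. ITGB1, which encodes an integrin subunit, rose from an intensity of 52.3 ± 3.10 (SD, n = 4) to 531 ± 217, a log2 difference of 4.02 ± 0.48 (SE; limma adjusted p = 7.1e-05). ACTB, the gene of beta-actin and a described HuR target, rose from 70.0 ± 12.9 to 612 ± 280 (2.84 ± 0.35, limma adjusted p = 7.5e-05). CCND2, a D-type cyclin gene, was at least 5.91-fold higher and CDH2, the N-cadherin gene, at least 3.92-fold higher in HuR IPs. Such bounds are given where a probe was detected at p under 0.05 on no array of the dim group. Its values there were raised to the lowest signal of a probe detected at p under 0.01 on the same array. Bounds hold on the background-corrected, normalized scale alone. ITGB1 was detected on 1 of 4 IgG arrays. The other CCND2 probe gave 1.59 on the log2 scale, which is less than the bound. The other ACTB probes gave 0.91 and 4.06. RN7SL1, the signal recognition particle RNA, rose by 2.03 ± 0.40 (2 of 4 IgG arrays detected it), and TUBA3FP, a tubulin pseudogene whose probe may share signal with tubulin genes, by 1.99 ± 0.51. ROCK2, a kinase of the actin cytoskeleton, rose by 1.93 ± 0.42, but its other probe gave -0.08. FARSB (1.86 ± 0.42), ITIH5 (1.84 ± 0.34), PCLAF, a PCNA-associated factor (1.80 ± 0.54), and ORC6, a subunit of the replication origin complex (1.77 ± 0.23), rose as well. PCLAF did not pass without replicate 2 of the IgG IPs or replicate 1 of the HuR IPs with control siRNA (highest limma adjusted p = 0.0681).

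All 3 tested members of the extracellular matrix and adhesion list rose: ITGB1, CD44 (at least 1.79-fold) and THBS1 (at least 1.26-fold); 3 passed when adjusted over the list alone. The camera adjusted p was 0.00194 with the preset correlation and the adjusted p was 0.149 with an estimated correlation. Of 6 tested literature targets of HuR, ACTB, CASP2 (at least 1.37-fold) and THBS1 rose and none fell, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.149 with an estimated correlation). Both tested G1/S genes rose, UHRF1 by at least 1.79-fold and CDK6 by at least 1.02-fold, and 2 remained when adjusted over the list alone. Of 5 tested G2/M genes, 2 rose, UBE2C (at least 2.03-fold) and BUB3 (0.69 ± 0.16, detected on 3 of 4 IgG arrays), and 2 when adjusted over the list alone, with a camera adjusted p of 0.241. SRSF6, a splicing factor gene (at least 2.43-fold), and SRSF9 (at least 1.11-fold) rose among 6 splicing and hnRNP genes, 2 when adjusted over the list alone (camera adjusted p = 0.436). ZMAT3, a p53 target, rose by 1.07 ± 0.23 and the zinc finger gene ZNF430 by 1.01 ± 0.26, each detected on 1 of 4 IgG arrays. Of 4 housekeeping genes, ACTB, YWHAZ (at least 2.32-fold) and the glycolytic gene PGK1 (at least 1.10-fold) rose and GAPDH fell, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.106). CDK6 did not pass without replicate 1, 2, 3 or 4 of the IgG IPs with control siRNA (highest limma adjusted p = 0.0661), nor PGK1 without replicate 3 or 4 of them (0.0627).

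Ribosomal protein mRNAs were lower in HuR than in IgG IPs with control siRNA after quantile normalization, but not in intensity. Of 36 tested members, 14 fell and none rose, and 19 fell when adjusted over the list alone (camera adjusted p = 6.3e-08; adjusted p = 0.180 with an estimated correlation). RPS29 fell by 2.15 ± 0.25 on the log2 scale while its deposited intensity was 129.5 ± 23.3 (SD, n = 4) in IgG and 129.8 ± 33.5 in HuR IPs. GAPDH, a glycolytic enzyme gene, fell by 2.07 ± 0.51 with intensities of 116 ± 12.2 and 108 ± 3.50. RTEL1, a DNA helicase gene, fell by 2.68 ± 0.58, with intensities of 147 ± 10.3 and 122 ± 11.1. RPL41 (-2.34 ± 0.56), RPS12 (-1.86 ± 0.51), RPS16 (-1.85 ± 0.44), the elongation factor gene EEF1A1 (-1.83 ± 0.31), RPS24 (-1.64 ± 0.53), TPT1 (-1.17 ± 0.28), LDHA (-0.83 ± 0.21, detected on 3 of 4 HuR arrays) and CHCHD2 (at least 1.31-fold lower) followed. RPS24 did not pass without replicate 2 or 4 of the IgG IPs or replicate 1, 2 or 4 of the HuR IPs with control siRNA (highest limma adjusted p = 0.0856). Other probes gave -0.70 for GAPDH, -2.33 and -1.05 for RPS29, and -0.46 and -0.52 for EEF1A1. Without scaling the median difference of the 36 ribosomal protein genes was -0.016, against -0.81 after quantile normalization. With median centring it was -0.18. Without replicate 2 of the HuR IPs with MIR100HG siRNA, an array outside this comparison, it was -0.58 with quantile normalization, -0.12 with median centring (3 of 32 members higher, 3 lower) and changed sign to 0.019 without scaling (4 higher, 0 lower). Of 7 translation factor genes, 4 rose, among them EIF4G2 (1.24 ± 0.27, detected on 1 of 4 IgG arrays; other probe 0.69) and EIF4B (at least 1.21-fold), and EEF1A1 and TPT1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.436). PGK1 rose and GAPDH and LDHA fell among 4 glycolysis genes (camera adjusted p = 0.158), and none of 6 oxidative phosphorylation genes passed (camera adjusted p = 0.241).

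The test was limma over all 16 arrays, with 1387 genes and unnamed probes tested. It called 293 higher and 70 lower in HuR IPs with control siRNA, and 474 at an unadjusted p under 0.05. Of the 293, 154 were detected at p under 0.05 on no control-siRNA IgG array. Of the 70, 4 were detected on no control-siRNA HuR array. The filter could let a gene in through a single group of 4 arrays. The split was 10 higher and 0 lower without scaling between arrays. It was 259 higher and 22 lower with quantile normalization within each IP type and then median centring. The total of 363 became 232 without replicate 1 and 236 without replicate 2 of the HuR IPs with control siRNA, and 44 with median centring. Leaving out replicate 2 of the HuR IPs with MIR100HG siRNA gave 303, of which 226 higher and 77 lower. The same omission with other scalings, added after seeing the data, gave 273 higher and 83 lower with median centring, and 295 and 11 without scaling. The median difference of all tested genes was -0.05, and 0.07 without scaling. Over all comparisons, 80 gene results passed by the naming rule; of 77 whose probe also stood for the gene there, 9 still passed with median centring and 2 without scaling. With that array left out as well, 55 and 56 of 71 did.

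**Figure D1:**
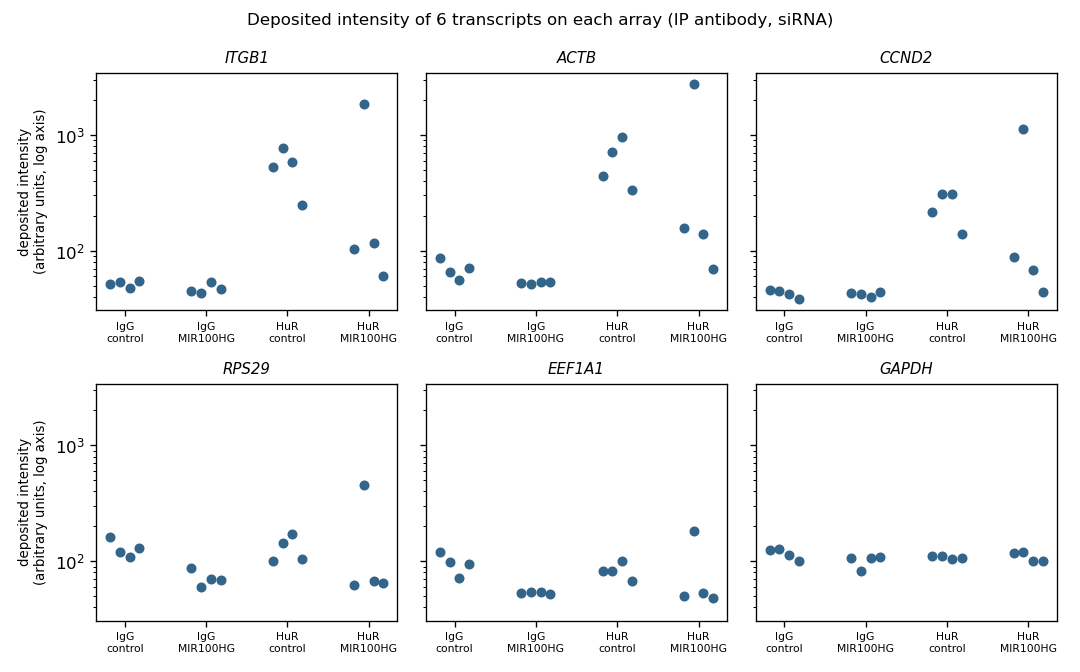
Deposited intensity (arbitrary units, log axis) of ITGB1, ACTB, CCND2, RPS29, EEF1A1 and GAPDH on each of the 16 arrays, with 4 points per group of antibody and siRNA. ITGB1, ACTB and CCND2 are brighter in HuR than in IgG IPs with control siRNA, while RPS29 averages 129.5 and 129.8 in those groups and GAPDH 116 and 108.

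With MIR100HG siRNA, HuR IPs on average also held more ACTB and ITGB1 mRNA than IgG IPs. ACTB rose by 3.20 ± 0.35 on the log2 scale (limma adjusted p = 2.1e-05), with 0.087 and 3.63 for its other probes, and ITGB1, detected on 1 of 4 IgG arrays, rose by 2.60 ± 0.48 (limma adjusted p = 0.00534). JUND, an AP-1 transcription factor gene, was at least 6.74-fold higher. Other rises were FAM177A1 (2.39 ± 0.41, detected on 2 of 4 IgG arrays), SLC7A5P2 (1.84 ± 0.41), RN7SL1 (1.72 ± 0.40, detected on 1 of 4), RRP7BP (1.35 ± 0.31, detected on 3 of 4), LAIR1 (1.09 ± 0.26) and CLUAP1 (0.89 ± 0.19). POTEF was at least 3.74-fold higher, but it is a paralog of ACTB and its probe may share that signal. Replicate 4 of these HuR IPs stood apart in normalized log2 intensity. There ITGB1 was at 4.82, against 7.43 to 7.89 on the other HuR arrays and 4.78 on replicate 3 of the IgG IPs. POTEF was at 4.25 there, against 7.26 to 7.86 on the other HuR arrays, and ACTB at 6.74, against 8.40 to 8.48. PRICKLE2 fell by 1.64 ± 0.36 and RHBDL3 by 0.88 ± 0.24 after quantile normalization, while intensity was higher in HuR IPs, at 67.5 ± 4.04 (SD, n = 4) against 63.75 ± 5.25 and 63.0 ± 3.56 against 57.25 ± 0.957. Over the other settings their differences came as near to 0 as -0.096 and -0.0072. RPS29 fell by 2.34 ± 0.25 after quantile normalization, but its difference was 0.22 with median centring and 0.46 without scaling. Its other probes gave -2.48 and -0.00054. RPL37A, detected on 3 of 4 HuR arrays, fell by 1.64 ± 0.31, but its difference was 0.14 without scaling, and -0.34 when replicate 2 of the HuR IPs with MIR100HG siRNA was left out too. Over all 16 arrays the median of all tested genes was 0.27 without scaling, against 0.08 after quantile normalization. Of 36 ribosomal protein genes, 2 fell, and 2 when adjusted over the list alone (camera adjusted p = 6.6e-04; adjusted p = 0.333 with an estimated correlation); the list's median was -0.20 and changed sign to 0.13 with median centring and 0.37 without scaling. When that array was left out the median was -0.37 with quantile normalization, -0.33 with median centring and -0.17 without scaling. ACTB was the member that passed among 6 literature targets, 1 when adjusted over the list alone (camera adjusted p = 0.0790), and ITGB1 the member that passed among 3 adhesion genes, 1 when adjusted over the list alone (camera adjusted p = 0.0790).

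Several of these calls rested on single arrays. RHBDL3 passed in 1 of 16 fits that left out an array, the one without replicate 4 of the HuR IPs with MIR100HG siRNA, and its highest limma adjusted p was 0.151. Without replicate 1 or 3 of the HuR IPs with MIR100HG siRNA, SLC7A5P2 and POTEF did not pass (highest limma adjusted p = 0.0558 for both). RRP7BP did not pass without replicate 2 or 3 (0.0577), and RN7SL1 without replicate 1, 2 or 3 of that group or replicate 4 of the IgG IPs with MIR100HG siRNA (0.0656). LAIR1 did not pass without replicate 1 or 3 of the HuR IPs or replicate 2 or 4 of the IgG IPs with MIR100HG siRNA (0.0827). PRICKLE2 did not pass without replicate 1 of the HuR IPs or replicate 3 or 4 of the IgG IPs with MIR100HG siRNA (0.0602).

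In limma, 43 genes were higher and 15 lower in HuR IPs with MIR100HG siRNA, and 199 had an unadjusted p under 0.05. Of the genes called in control-siRNA cells, 39 were also higher here, where 9.08 would be by independent lists, and 6 also lower, where 0.757 would be. The split was 49 higher and 0 lower with quantile normalization within each IP type, 42 and 7 with per-array z-scores, and 0 and 0 with median centring or without scaling (105 and 296 at an unadjusted p under 0.05). It was 37 and 12 without replicate 2 of the HuR IPs with MIR100HG siRNA, and with the other scalings added 7 and 0 with median centring and 30 and 0 without scaling. In the mean of both enrichments limma called 300 higher and 89 lower, 143 and 0 without scaling, and 239 and 25 with quantile normalization within each IP type. Without that array they were 222 and 93 with quantile normalization, 243 and 81 with median centring and 313 and 6 without scaling. The total of 58 became 32 without replicate 4 of the IgG IPs with MIR100HG siRNA, and 23, 22 and 94 without replicates 1, 3 and 4 of the HuR IPs with MIR100HG siRNA.

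The difference between these enrichments, the question of the series, rested on 5 transcripts. The 1 named gene, C6orf62, passed as lower with MIR100HG siRNA (limma adjusted p = 0.0476). It was detected at p under 0.05 on 4 of 4 HuR IPs with control siRNA, on 1 of 4 with MIR100HG siRNA and on 0 of 8 IgG IPs, so the size of the difference cannot be read. Its intensity was 45.3 ± 1.71 (SD, n = 4) and 42.5 ± 1.29 in IgG IPs with control and MIR100HG siRNA, and 89.5 ± 21.3 and 63.3 ± 32.7 in HuR IPs. The unnamed probes ILMN_2383934 and ILMN_1708416 also passed as lower, and were likewise detected on 0 of 8 IgG IPs, on 4 of 4 HuR IPs with control siRNA and on 0 and 1 of 4 with MIR100HG siRNA. ILMN_1695261 and ILMN_3201843 passed as higher, and were detected on 1 and 0 of 4 IgG IPs and each on 1 of 4 HuR IPs with MIR100HG siRNA. With control siRNA both were detected on 4 of 4 IgG IPs and 3 of 4 HuR IPs. With MIR100HG siRNA their normalized log2 means went from 6.26 to 4.29 and from 6.03 to 4.32 in IgG IPs. In HuR IPs they went from 4.70 to 4.38 and from 4.67 to 4.42, so on that scale neither rose with HuR. These 5 fell outside the rule for named genes and were chosen after their values were seen. RPL31 (limma adjusted p = 0.0735), YWHAZ (limma adjusted p = 0.0794), UBE2C, UHRF1 and THBS1 (limma adjusted p = 0.148 for each of these 3) did not pass over all 16 arrays. Without replicate 2 of the HuR IPs with MIR100HG siRNA YWHAZ (limma adjusted p = 1.2e-04), UBE2C (1.6e-04) and UHRF1 (1.7e-04) passed as lower, also with median centring. They were then detected in HuR IPs with control siRNA alone, so no size is given. RPL31 passed as higher there (limma adjusted p = 0.0224), but not with median centring (limma adjusted p = 0.349). None of 36 ribosomal protein genes passed, 1 when adjusted over the list alone (camera adjusted p = 0.00120, upward; adjusted p = 0.537 with an estimated correlation). That list's median, 0.50 here, was 0.02 with quantile normalization within each IP type. Without replicate 2 of the HuR IPs with MIR100HG siRNA it changed sign to -0.19 with median centring and -0.18 without scaling. None of 3 adhesion genes passed, 1 when adjusted over the list alone (camera adjusted p = 0.0124, downward; adjusted p = 0.537 with an estimated correlation).

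Limma called 2 genes higher and 3 lower for this difference, and 171 at an unadjusted p under 0.05. The split was 0 and 1 with per-array z-scores and with quantile normalization within each IP type, and 0 and 0 with median centring or without scaling (63 and 140 at an unadjusted p under 0.05). Leaving out replicate 2 of the HuR IPs with MIR100HG siRNA gave 134 genes, 18 higher and 116 lower, and the same omission, added after seeing the data, gave 279 with median centring and 260 without scaling. All 116 lower genes, 81 of them named, were among those higher in HuR IPs with control siRNA, and 116 were also lower with median centring, while 7 of the 18 higher genes held. The overlap is in part built in, since both comparisons use the same HuR IPs with control siRNA. Of the 116, 105 were undetected at p under 0.05 in at least 1 group and 59 in both IgG groups, so the size of most of these differences cannot be read. These counts hold only if that array is set aside, and whether it should be is open. The count was 8 without replicate 1 of the IgG IPs with MIR100HG siRNA. It was between 1 and 3 without any replicate of the IgG IPs with control siRNA or without replicates 2, 3 or 4 of the IgG IPs with MIR100HG siRNA. It was also between 1 and 3 without replicates 1, 2 or 3 of the HuR IPs with control siRNA, or 1 or 3 of those with MIR100HG siRNA. The median of all tested genes was 0.0038, and 0.12 without scaling and with quantile normalization within each IP type.

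The 300 genes higher in the mean of both HuR enrichments were also scored as a set, as their mean log2 intensity minus that of the other tested genes. The score was 0.91 ± 0.09 (SD, n = 4) in HuR IPs with control siRNA and -0.37 ± 0.07 and -0.47 ± 0.05 in IgG IPs with control and MIR100HG siRNA. In HuR IPs with MIR100HG siRNA it was 0.10, 1.07, 0.05 and -0.36 on replicates 1 to 4. Replicate 2 correlated with the HuR IPs with control siRNA at 0.823 to 0.906 and with its own group at 0.0278 to 0.409. The interaction of the score was -0.60 (two-sided exact permutation p = 0.142, adjusted p = 0.214), and the difference among HuR IPs -0.70 (exact permutation p = 0.143, adjusted p = 0.214). The fit without replicate 2 chose the set again, with 222 genes. There the interaction was -0.64 (exact permutation p = 0.0412) and the difference among HuR IPs -0.75 (exact permutation p = 0.0286, the smallest those arrays allow). For the 6 literature targets the interaction was -0.13 (exact permutation p = 0.354) and the difference among HuR IPs -0.22 (exact permutation p = 0.0286, adjusted p = 0.171); the interaction was 0.02 without replicate 1 of the HuR IPs with control siRNA. Of the 293 genes higher in HuR IPs with control siRNA, 64, 289, 70 and 24 were detected at p under 0.01 on replicates 1 to 4 of the HuR IPs with MIR100HG siRNA, and 292, 291, 293 and 217 on the HuR IPs with control siRNA, on which they were chosen.

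**Figure D2:**
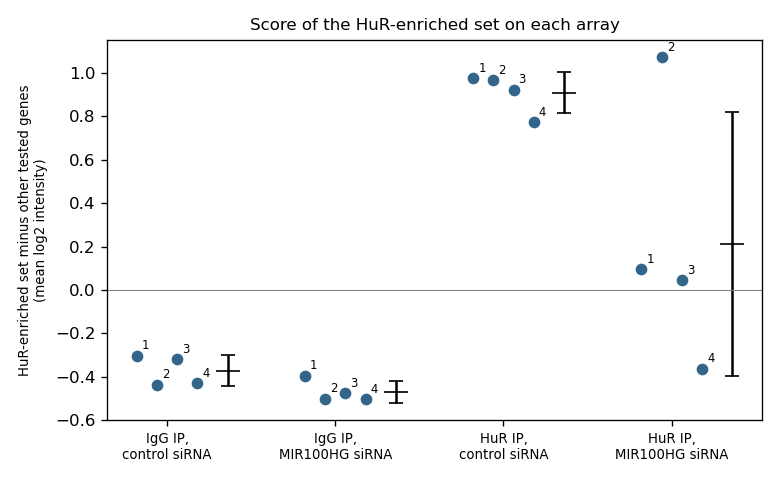
Score of the HuR-enriched set (mean log2 intensity of its 300 genes minus that of the other tested genes) on each array, numbered by replicate, with the mean and SD of each group of 4 beside the points. Replicate 2 of the HuR IPs with MIR100HG siRNA, at 1.07, lies above the 4 HuR IPs with control siRNA, and replicates 1, 3 and 4, at 0.10, 0.05 and -0.36, below them.

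Within HuR IPs, YWHAZ, UHRF1, ZMAT3, UBE2C and THBS1 mRNAs were lower with MIR100HG siRNA. YWHAZ, a 14-3-3 protein gene, fell by 1.45 ± 0.24 on the log2 scale (limma adjusted p = 0.00148), from an intensity of 111 ± 35.2 (SD, n = 4) to 85.8 ± 80.9, the latter with replicate 2 included. UHRF1 fell by 1.06 ± 0.20, ZMAT3 by 1.14 ± 0.23, UBE2C by 1.14 ± 0.23 and THBS1 by 0.77 ± 0.15. All 5 were detected with MIR100HG siRNA on replicate 2 alone, so the size of these falls rests on background values of replicates 1, 3 and 4. TRIM16L (-1.61 ± 0.44), PPIL3 (-1.24 ± 0.37), RRP7BP (-1.04 ± 0.31), DCBLD2 (-0.99 ± 0.27) and TP53BP2 (-0.94 ± 0.24, detected on 2 of 4 arrays with MIR100HG siRNA) also fell. RPS20 (-1.38 ± 0.34) and RPS3 (-1.21 ± 0.24), each detected on 1 of 4 arrays with MIR100HG siRNA, were the 2 ribosomal protein genes of 36 that fell, 2 when adjusted over the list alone (camera adjusted p = 0.00382; adjusted p = 0.483 with an estimated correlation). With replicate 2 of the HuR IPs with MIR100HG siRNA left out, 14 of 32 fell (camera p = 0.175 with an estimated correlation). EIF4G2 (-0.89 ± 0.27, detected on 2 of 4 arrays with MIR100HG siRNA) and EIF4B (-0.68 ± 0.21, detected on 1 of 4) fell among 7 translation factor genes, 3 when adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.421 with an estimated correlation). THBS1 fell among 3 adhesion genes, 3 when adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.421 with an estimated correlation). THBS1 was also the member that fell among 6 literature targets, 2 when adjusted over the list alone (camera adjusted p = 0.309), and YWHAZ among 4 housekeeping genes, 1 when adjusted over the list alone (camera adjusted p = 0.309). The noncoding host transcript SNHG3, detected on 2 of 4 arrays with MIR100HG siRNA, fell by 0.65 ± 0.19. Other probes gave -0.56 for EIF4G2 and -1.46 for DCBLD2.

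EIF4G2 did not pass in 15 of 16 fits that left out an array (highest limma adjusted p = 0.172), and EIF4B in 11 of 12 (0.146). PPIL3 (0.143) and RRP7BP (0.155) did not pass in 12 of 16, and SNHG3 (0.137) in 11 of 16. For these 5 genes the omitted arrays came from all groups for EIF4G2, PPIL3 and RRP7BP, from both IgG groups and the HuR IPs with MIR100HG siRNA for EIF4B, and from every group but the IgG IPs with control siRNA for SNHG3. TRIM16L did not pass without replicate 1, 2, 3 or 4 of the HuR IPs with control siRNA or replicate 3 or 4 of those with MIR100HG siRNA (0.113). DCBLD2 did not pass without replicate 1, 2 or 3 of the former or 1, 3 or 4 of the latter (0.108). TP53BP2 did not pass without replicate 1 or 2 of the former or 1 or 4 of the latter (0.0938), and RPS20 without replicate 3 of the former or 1, 3 or 4 of the latter (0.0632).

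Limma called 0 genes higher and 128 lower in this comparison, and 375 at an unadjusted p under 0.05. The split was 185 higher and 187 lower with quantile normalization within each IP type and then median centring. It was 104 and 268 without replicate 2 of the HuR IPs with MIR100HG siRNA, and 0 and 4 without scaling. With that array left out, the other scalings gave 166 and 374 with median centring and 42 and 388 without scaling. With quantile normalization within each IP type the median of all tested genes was 0.15, against -0.0022 over all 16 arrays together. The total became 58, 59 and 54 without replicates 1, 3 and 4 of that group, and 60, 59 and 61 without replicates 1, 2 and 3 of the HuR IPs with control siRNA.

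IgG IPs, the background, differed between the siRNAs as well, in EEF1A1 and in 14 of 36 tested ribosomal protein genes among others. EEF1A1 fell by 2.38 ± 0.31 on the log2 scale with MIR100HG siRNA (limma adjusted p = 1.6e-04), from an intensity of 96.5 ± 19.7 (SD, n = 4) to 53.3 ± 0.957. Its other probes gave -0.67 and -0.40, and the other RPL11 probe -1.24. RPL41 (-2.00 ± 0.56), RPS12 (-1.98 ± 0.51), RPS16 (-1.94 ± 0.44), RPS20 (-1.61 ± 0.34) and RPL11 (-1.41 ± 0.27) fell, and RPS10 was at least 2.27-fold lower. With MIR100HG siRNA, RPS12, TMSB10 and LDHA were detected on 2 of 4 IgG arrays and RPS16, TPT1 and RRP7BP on 3 of 4. Of 36 ribosomal protein genes 14 fell and none rose, with 19 lower when adjusted over the list alone (camera adjusted p = 1.1e-14; adjusted p = 0.188 with an estimated correlation). The list's median was -0.80, and it was -0.50 with median centring and -0.59 without scaling. With replicate 2 of the HuR IPs with MIR100HG siRNA left out, 15 of 32 fell with quantile normalization, 16 with median centring and 18 without scaling. RRP7BP (-1.67 ± 0.31), the thymosin gene TMSB10 (-1.34 ± 0.26), TPT1 (-1.14 ± 0.28) and LDHA (-0.86 ± 0.21) also fell, SNHG3 was at least 1.30-fold and COX6C, a cytochrome oxidase subunit gene, at least 1.15-fold lower, and G3BP2, a stress granule protein gene, rose by 1.18 ± 0.25 (detected on 3 of 4 arrays with control siRNA), with intensities of 56.25 ± 1.71 and 58.0 ± 2.94. Of 7 translation factor genes 2 fell, 2 when adjusted over the list alone (camera adjusted p = 0.158). LDHA was 1 of 4 glycolysis genes and COX6C 1 of 6 oxidative phosphorylation genes, with 1 and 2 lower when adjusted over the list alone (camera adjusted p = 0.525 for both).

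RPL41 did not pass in 11 of 16 fits that left out an array, among them replicates 1, 2 and 4 of the IgG IPs with control siRNA and 2 and 3 of those with MIR100HG siRNA (highest limma adjusted p = 0.145). The others were replicates 1, 2, 3 and 4 of the HuR IPs with control siRNA and 1 and 3 of those with MIR100HG siRNA. RPS12 did not pass without replicate 1, 2 or 4 of the IgG IPs with control siRNA or 2, 3 or 4 of those with MIR100HG siRNA (0.105). LDHA did not pass without replicate 2 or 4 of the former or 2, 3 or 4 of the latter (0.0680), TPT1 without 1 or 2 of the former or 2 of the latter (0.0759), COX6C without 1 of the former or 3 of the latter (0.0766), and RPS16 without 2 or 3 of the latter (0.0537).

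Limma called 7 genes higher and 73 lower among IgG IPs, and 230 at an unadjusted p under 0.05. With median centring (64 at an unadjusted p under 0.05) or without scaling (74), 0 passed. With quantile normalization within each IP type and then median centring (84), 0 passed as well. Without replicate 2 of the HuR IPs with MIR100HG siRNA, an array outside this comparison, 103 passed with quantile normalization, 81 with median centring and 97 without scaling. The total of 80 became 50 without replicate 1 of the IgG IPs with control siRNA, and 50 and 46 without replicates 2 and 3 of those with MIR100HG siRNA. In the HuR and IgG comparisons 14 genes were lower in both, where 6.74 would be by independent lists (Fisher's exact p = 0.00581). That test takes genes as independent, so its p does not measure the spread between samples.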

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

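Tests of a swap, of an effect in every replicate, of MIR100HG depletion in 3 cultures, of quantile scaling in either ribosomal pattern, of level-matched transcripts and of which arrays the other splits put together were chosen after the result was seen.

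A check for a sample far from the other 3 of its group covered 4 measures per array and every named gene past the threshold, in all 4 groups. It singled out 42 of 252 groups, where chance gives about 1 in 20, or 12.6. Of the 42, 18 were replicate 2 of the HuR IPs with MIR100HG siRNA. That array was high in detected probes (2592), in highest intensity (6370) and, in normalized log2 intensity, in EEF1A1 (5.31), ZMAT3 (5.32), UBE2C (5.53), YWHAZ (5.42), UHRF1 (5.26), CASP2 (5.44), SRSF9 (4.92) and EIF4B (4.77). It was also high in THBS1 (4.62), PGK1 (5.09), CDK6 (5.02), LAIR1 (9.77), RPS20 (5.28), RPS3 (4.67), TMSB10 (4.76) and RPS10 (5.57). Replicate 4 of the same group was low in ACTB (6.74), PCLAF (5.39), ITGB1 (4.82) and POTEF (4.25).

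Among HuR IPs with control siRNA, replicate 1 was low in RPL41 (5.54) and RPL11 (4.85), replicate 4 in CD44 (5.26) and replicate 3 in LAIR1 (9.21). Replicate 2 was high in ORC6 (7.17), and replicate 3 in RPS3 (5.67) and COX6C (4.75). Among IgG IPs with control siRNA, replicate 1 was high in highest intensity (413) and ZMAT3 (5.18), and replicate 3 in TRIM16L (6.86). Among IgG IPs with MIR100HG siRNA, replicate 1 was high in ITIH5 (5.89), TUBA3FP (6.07), RPS12 (7.35), CHCHD2 (4.72), TRIM16L (5.89) and RPS3 (5.04). Replicate 2 was high in RHBDL3 (6.44), replicate 3 in ITGB1 (4.78), and replicate 4 in DCBLD2 (5.88) and TP53BP2 (4.41).

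The siRNA effect differed between HuR and IgG IPs for 5 genes by the interaction test, C6orf62 (-1.17) among them, a fitted value against groups at background. In data outside the comparisons, the deposited score column of the IgG IP with MIR100HG siRNA, replicate 1, correlated with its array at 0.0066. The probe of BLID, a gene of the MIR100HG locus that fell outside the detection filter, was detected at p under 0.05 on 3 arrays, all HuR IPs with MIR100HG siRNA. Those arrays detected 3214 to 5836 of 47231 probes at that p. Its normalized log2 intensity on them, 4.44 to 4.54, overlapped that of other groups, which reached 4.49. No effect of the siRNA on BLID is read from this.

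Replicates 1, 3 and 4 of the HuR IPs with MIR100HG siRNA lacked most of the HuR-enriched mRNAs that replicate 2 held. No control-siRNA HuR IP scored like them: the lowest control score, 0.77, lay 0.68 above the highest of the 3 arrays. This argues against a swap with a control-siRNA HuR IP only if every HuR IP with MIR100HG siRNA scores low. That is not known, so a swap is not excluded. As labelled, replicate 2 had no lowered score: it lay 0.098 above the highest control-siRNA array (SD of those 4, 0.094). It is a single array, defines the pattern and may be wrongly labelled. The rule asked for more than 1 array above the controls, so it could not decide whether recovery was lowered in all 4 replicates or in 3. Less RNA recovered or amplified on the 3 arrays may explain the pattern: the median unscaled ribosomal protein level lay below every control-siRNA HuR IP on 3 of the 3. It was 4.25 to 4.37 on them, 4.79 to 5.49 on control-siRNA HuR IPs and, on replicate 2, 6.68, above every other array. The IgG IPs with MIR100HG siRNA, at 4.37 to 4.68, also lay below the control-siRNA HuR IPs, so a low level was not particular to the 3 arrays. Whether MIR100HG was depleted in 3 cultures and not in replicate 2 cannot be told apart, since its probe was at background there (detection p 0.147) and on every other array, and a wrong label of replicate 2 alone and an siRNA effect on HuR binding stay open.

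In IgG IPs 14 of 36 tested ribosomal protein mRNAs passed as lower with MIR100HG siRNA, a list call that did not hold with an estimated correlation (adjusted p = 0.188), and over all 16 arrays 0 genes passed with median centring or without scaling. Quantile scaling as the cause is argued against by unscaled values, in which the mean of the array medians differed by -0.65, with the highest MIR100HG-siRNA array at 4.68 and the lowest control at 4.82. Other transcripts fell by 0.212 of the list's change, under the bound written beforehand as evidence against less RNA on these arrays. That bound was wrong, since those transcripts were dimmer (median level 4.68 against 5.06) and had less room to fall: 83 matched on control level fell by 0.55, or 0.930 of the list's change (95% bootstrap interval 0.396 to 1.27), though such matching carries regression to the mean. The bootstrap resampled transcripts and not arrays, so its interval does not measure the spread between samples. Less RNA on these arrays and a change of background mRNAs with the siRNA therefore cannot be told apart.

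In HuR IPs with control siRNA GAPDH and 14 of 36 ribosomal protein mRNAs passed as lower than in IgG IPs (list adjusted p = 0.180 with an estimated correlation). Quantile scaling may explain it: without scaling the median difference of the ribosomal protein list was -0.016, against -0.81, and 0.019 without replicate 2 of the HuR IPs with MIR100HG siRNA. The prediction also asked for no gene lower without scaling. This held over all 16 arrays (0) but not without that array, where 11 of 1149 tested genes were lower. No ribosomal protein gene was among those 11, so the fall of that list was not seen without scaling in either fit. The prediction as written was not met without that array, so the explanation stays open. No biological explanation of this pattern was tested.

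Other splits of the samples into groups of the same size were fitted for each count. For the HuR enrichment with control siRNA 1 of 35 splits, the real one, gave as many as 363 genes, and the highest other gave 0. With MIR100HG siRNA it was again 1 of 35, with 58 genes, but the highest other came close, at 50. The real split also ranked first for the siRNA effect in IgG IPs (1 of 35, 80 genes, highest other 26) and the mean enrichment (1 of 100, 389 genes, highest other 156). A share of 1 of 35 is the smallest possible and was not adjusted over the counts. Ranking first therefore argues against chance but does not exclude it. For the enrichment with MIR100HG siRNA and the siRNA effect in IgG IPs, 0 genes passed with median centring or without scaling. The splits were not run with those scalings. Chance cannot be excluded for the siRNA effect in HuR IPs, where 3 of 35 splits gave as many as 128 genes and the highest other 333. The 4 other splits with any calls (333, 147, 124 and 120 genes) were those that put replicate 2 of the MIR100HG-siRNA group with 3 control-siRNA arrays. The split with 333 genes left control-siRNA replicate 4 with the other MIR100HG-siRNA arrays. Nor can chance be excluded for the interaction, where 8 of 100 gave as many as 5. The highest other, 375, was several times the real count, which points to a structure of the samples. Of the 7 other splits with as many, 6 put replicate 2 of the MIR100HG-siRNA HuR IPs with control-siRNA HuR IPs 1, 2 and 3. These left control-siRNA replicate 4 with the other MIR100HG-siRNA HuR IPs. Of 13 splits that put replicate 2 with 3 control-siRNA HuR IPs, only these 6 had calls. The highest among the rest had 9 genes.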

How the results depend on the processing

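Median centring and no scaling, each without replicate 2 of the HuR IPs with MIR100HG siRNA, and a stricter detection threshold for the MIR100HG and ELAVL1 probes were chosen after the data were seen. Scores of the HuR-enriched set below used a set chosen again in each fit, not the same 300 genes. Signal close to background limits every result. Over all 16 arrays most counts fell several-fold with median centring or no scaling. Once replicate 2 of the HuR IPs with MIR100HG siRNA was left out such a fall remained with median centring for the enrichment with MIR100HG siRNA alone. Except where fewer genes, groups or arrays entered the fit, the cause was not tested.

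Counts below are in the order HuR enrichment with control siRNA, with MIR100HG siRNA, interaction, siRNA effect in HuR IPs, in IgG IPs, and mean enrichment, against 363, 58, 5, 128, 80 and 389. With median centring they were 44, 0, 0, 36, 0 and 107, and without scaling 10, 0, 0, 4, 0 and 143. In both, the literature target score was -0.32 in HuR IPs (exact permutation p = 0.200) and changed sign to 0.013 in IgG IPs. With z-scores per array the interaction had 1 gene and the siRNA effect in HuR IPs 201. With quantile normalization within each IP type and then median centring the interaction had 1, the siRNA effect in HuR IPs 372 and in IgG IPs 0. Without background correction the interaction had 1 gene and the literature score in HuR IPs was -0.22; with normexp without negative controls these were 2 and -0.18 (exact permutation p = 0.0571 for both scores). With the deposited scores the enrichment with MIR100HG siRNA had 0 genes, the interaction 1 and the siRNA effect in IgG IPs 4. The literature score was then -2.22 (exact permutation p = 0.0159), and 0.21 in IgG IPs, a change of sign.

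Without a filter on dim probes 37164 genes were tested and the counts were 139, 8, 2, 31, 25 and 145. The HuR-enriched score in IgG IPs was then -0.19 (exact permutation p = 0.0286) and the literature score in HuR IPs -0.073. With probes detected on all 16 arrays, 30 were tested and the counts were 8, 10, 0, 0, 3 and 18, and the HuR-enriched score changed sign to 0.14. With detection on at least 1 array the enrichment with MIR100HG siRNA had 10 genes, the siRNA effect 62 in HuR and 40 in IgG IPs, and the literature score in HuR IPs was -0.12. With array weights, 0.146 for replicate 2 of the HuR IPs with MIR100HG siRNA, the interaction had 174 genes and the siRNA effect in HuR IPs 561. An intensity trend with robust estimation gave 11 for the interaction. With only the groups of each contrast, the enrichment with MIR100HG siRNA had 9 genes and the siRNA effect 81 in HuR and 34 in IgG IPs. A fold of at least 1.5 left 254 for the mean enrichment.

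Replicate numbers are shared between groups. Over 24 pairs each, arrays of the same number had a mean r of 0.010 by title and 0.023 by IP number, against -0.0049 and -0.0091 for other numbers. Only 4 and 5 pairs exceeded 0.1, so the numbers were not taken to pair the samples. With the title number or the order of IP numbers as a replicate block the interaction had 2 genes each. The literature score in HuR IPs was -0.22 with the title number as a replicate block (exact permutation p = 0.125). That p is the smallest the blocked test allows, so it could not pass. A slide block was not run, since the files give no slide.

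Of 9 gene lists, camera passed 3, 1, 2, 3 and 1 in the first 5 comparisons. With an estimated correlation these were 0, 0, 0, 0 and 0, and fry, which asks whether a list's genes move on balance 1 way, gave 7, 5, 0 and 2 in all but the siRNA effect in HuR IPs.

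Leaving out 1 array at a time, the counts ranged from 232 to 369, 22 to 94, 1 to 134, 54 to 372, 46 to 117 and 278 to 400. The HuR-enriched score ranged from -0.67 to -0.42 for the interaction, -0.77 to -0.52 in HuR IPs and -0.16 to -0.081 in IgG IPs. The literature score ranged from -0.23 to 0.019, -0.31 to -0.15 and -0.18 to -0.056, with the positive value without replicate 1 of the HuR IPs with control siRNA. Detected probes ranged from 134.5 to 353 for HuR against IgG with control siRNA and -21.25 to 655 with MIR100HG siRNA. Between the siRNAs they ranged from -423.25 to 253 in HuR IPs, with -83.3 without replicate 4 of the HuR IPs with control siRNA, and from -271 to -117 in IgG IPs. The -271, without replicate 4 of the IgG IPs with MIR100HG siRNA, had an exact permutation p of 0.0286.

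With median centring and without replicate 2 of the HuR IPs with MIR100HG siRNA, 1149 genes were tested and the 6 counts were 356, 7, 279, 540, 81 and 324, against 303, 49, 134, 372, 103 and 315 with quantile normalization. The HuR-enriched score was -1.30 (exact permutation p = 0.0322), and -1.37 in HuR IPs, and the literature score -0.47 (0.0314). Without scaling and without that array the counts were 306, 30, 260, 430, 97 and 319 and the scores -1.05 (exact permutation p = 0.0245), -1.08 and -0.47. The p-values of the HuR-enriched score here follow in part from leaving out the array of its group that scored above the controls.

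Of single genes, RPS29 changed sign in the enrichment with MIR100HG siRNA, to 0.22 with median centring and 0.46 without scaling, and RPL37A to 0.14 without scaling. The other changes of sign were in the interaction, where none of these genes passed. CCN2 was 0.0052 and PMAIP1 0.20 with median centring, and CCN2 0.076, PMAIP1 0.27 and BUB3 0.025 without scaling. EEF1A1 was -0.024 and SNHG3 -0.12 with quantile normalization within each IP type. RN7SL1 ranged from -0.58 without replicate 1 of the IgG IPs with control siRNA to 0.17 without replicate 4 of the HuR IPs with MIR100HG siRNA. Without replicate 2 of that group, SNHG3 was -0.24, HNRNPD -0.23 and YBX1 -0.078 with median centring, and -0.22, -0.22 and -0.066 without scaling. MIR100HG and ELAVL1 were detected on 0 of 16 arrays at either threshold.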
